A study of Sus scrofa with 6 samples.

How the data were processed

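Total RNA of 6 samples of immature pig Sertoli cells was sequenced, 3 labelled Control and 3 labelled MT, and groups and replicate numbers were taken from the sample titles. The deposited table gives FPKM, which the authors computed by scaling fragments to gene length and library size, with a column per library and no pooling of replicates. The submitters' processing notes name bcl2fastq, HISAT2, featureCounts and Subread and the genome build Sscrofa11.1, with no versions of the tools. The annotation release, the strand setting, any filter and any scaling between libraries are not given in the sources used here. FPKM divides out both depth and gene length and is tied to the sum of each library, so a change in a few abundant transcripts moves all other values, and the counting decides how reads shared by gene copies are treated.

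Of the 20731 genes in the table, 13173 (63.5%) were given a symbol by matching their Ensembl identifiers, and 9483 of the 10950 tested genes had one. Coordinates were taken by symbol from the RefSeq annotation of Sscrofa11.1, the build the submitters name. No genome sequence was used here.

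Values of low genes rise in steps of 1 read, and 4727 low genes gave whole-number gene lengths and library totals. The totals lay within 0.0053 of whole numbers, between 19579279 and 21500665 reads, and the genes of the table held 99.6% of each total. All 10950 tested genes (100.0%) came out as whole reads within 0.01 of a whole number. The recovered number may be a whole fraction of the true one for a gene whose 6 read numbers share a divisor. At this depth 237 tested genes had fewer than 10 reads in at least 1 library, and for those counting error alone is large. Pairs of libraries of the same group differed by 6.4 to 151 times the sampling noise (chi-square per degree of freedom), so no library was taken as a copy of another.

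Genes with a mean of at least 1 FPKM over the 6 libraries were kept. MT was compared with Control on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, two-sided, group as the only term), with Benjamini-Hochberg adjustment over the 10950 genes and a threshold of 0.05. A log2 difference on this scale understates the change of low genes. A second count took genes past the threshold with a change of at least 2-fold. Gene lists were tested with camera of limma at its preset correlation of 0.01, two-sided, adjusted over the 36 lists with at least 3 tested members, and again with camera with an estimated correlation and with fry, whose directional p tests whether the genes of a list move on balance one way without comparing them with other genes. With an estimated correlation, camera also takes its degrees of freedom from the libraries rather than from the genes. For 7 of the 36 lists the median, the mean and the direction of camera differed in sign, and 0 of those 7 passed. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for reading, depth recovery and plots.

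The groups, the test, the filter, the 39 gene lists (974 genes, of which 692 were tested), the 20 genes of special interest, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named, where no gene passed, the 5 genes with the smallest p in each direction among genes with a symbol, up to 4 members with the smallest p of each list past camera, and the genes of special interest, 64 distinct genes in all, of which 3 are not reported here. Genes named outside this rule are said to be so, except members of the mitochondrial list, which were picked after their values were seen. The alternatives fixed beforehand were other pseudocounts, filters, scalings and variance models, sample weights, a replicate block, other set tests and leaving out each library. Those chosen after seeing the data were limma voom on recovered reads, scaling outside the mitochondrial genome, a term for the main within-group component, removal of a gene length trend, combinations of these without Control replicate 3, and camera with an estimated correlation and fry with each library left out. Ratios between mitochondrial mRNAs, each of these mRNAs relative to the mean of the 13, and the longer ones after a quadratic trend with log length was removed from each library, were also compared with limma.

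The model was tested on simulated data for the 10950 genes with 200 genes changed by known folds. With 6 libraries it recovered 51% of genes changed 2-fold and 88% of those changed 4-fold, with 6.1% false calls among 148 calls, and with the 5 libraries left without Control 3 it recovered 92% and 98%, with 5.9% false calls among 202. A shifted list of 22 genes was called in both cases and 0 of 100 unshifted lists. The simulated noise was independent between genes, which the real libraries are not.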

Results

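RNA was sequenced from 6 libraries of immature Sertoli cells of the pig, the somatic cells that surround and nourish the germ cells of the testis. The labels name 3 libraries as Control and 3 as MT, and the MT cells had been kept with melatonin, a hormone of the pineal gland, at 10 nM for 36 h. No dose or treatment time is given for the Control cells, so a matched solvent and time in culture cannot be assumed. Each library was given as FPKM, the fragments of a gene scaled to its length and to the size of the library, for 20731 genes. The library totals worked out from the steps of the low values were 19579279, 20028205 and 20961380 reads for Control replicates 1 to 3, and 21500665, 20484755 and 20711347 for MT replicates 1 to 3. The labels do not say whether the replicates came from separate cultures or animals, so every p-value measures only the spread between these libraries, which may be technical.

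The comparison of MT with Control asked which transcripts and which gene groups differ in Sertoli cells after melatonin. Genes of cholesterol synthesis and uptake fell as a group in MT cells, with a median log2 difference of -0.69 and all 22 tested members lower. The gene for INSIG1, a membrane protein of the endoplasmic reticulum that holds back the activators of sterol synthesis genes, stood at 20.7 ± 1.83 FPKM in Control and 7.10 ± 1.33 in MT (mean ± SD, n = 3). Genes of glutamine, serine and one-carbon metabolism rose as a group, with a median of 0.41 and 19 of 25 tested members higher. PHGDH, the enzyme that starts serine synthesis, stood at 109.6 ± 29.1 FPKM in Control and 240.4 ± 18.8 in MT (n = 3). Genes of S phase and DNA replication had a smaller median of -0.27, with 28 of 29 tested members lower. This list passed camera with an estimated correlation (adjusted p 0.040) but not the directional test fry (0.065), and with any library left out its adjusted p with an estimated correlation was 0.093 to 0.78. The cholesterol and glutamine lists passed both tests over 6 libraries. With an estimated correlation they still passed without MT 3 (0.049 each), but not without any other library (0.093 to 0.78). The test fry passed neither of them without Control 1, Control 2 or MT 1. Each fit without a library has fewer degrees of freedom, so a lost call does not show that a list rested on that library. With a library left out, the medians were -0.79 to -0.59 for cholesterol and 0.34 to 0.50 for glutamine.

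Taken gene by gene, 0 of 10950 tested genes passed an adjusted p of 0.05 in limma. The smallest adjusted p was 0.099, and 517 genes had an unadjusted p under 0.05 where chance alone gives 548. The same test by limma voom on the recovered read numbers also passed 0 genes, with 494 under an unadjusted p of 0.05. The 5 genes with the smallest p among those higher in MT were NUPR1, a stress-induced nuclear protein, KIF1A, a kinesin motor, ADGRA2, an adhesion receptor, CYTB, the mitochondrial cytochrome b, and IGFBP5, which binds insulin-like growth factors. NUPR1 (ENSSSCG00000040162, chromosome 3, 18402781 to 18404411) was at 12.2 ± 0.28 FPKM in Control and 27.7 ± 1.46 in MT, a log2 difference of 1.12 (SE 0.10, adjusted p 0.099). KIF1A (chromosome 15, 139610624 to 139694841) was at 1.37 ± 0.22 and 4.18 ± 0.27 FPKM, ADGRA2 (chromosome 15, 48572953 to 48611034) at 0.94 ± 0.17 and 3.96 ± 0.73, and IGFBP5 (chromosome 15, 118861816 to 118877787) at 21.8 ± 2.34 and 40.5 ± 4.09. The 5 with the smallest p among those lower in MT were SCD, the desaturase that makes monounsaturated fatty acids, INSIG1, ACAT2, the small nucleolar RNA SNORD38A and TNFSF14, a cytokine of the tumour necrosis factor family. SCD (ENSSSCG00000010554, chromosome 14, 111461560 to 111478033) was at 51.1 ± 5.74 FPKM in Control and 20.2 ± 2.54 in MT, a log2 difference of -1.30 (SE 0.14, adjusted p 0.099). TNFSF14 (chromosome 2, 72478178 to 72483885) was at 2.94 ± 0.55 and 1.07 ± 0.17 FPKM. SNORD38A was listed at 0 in the 3 MT libraries and rested on 2, 2 and 5 reads in the Control libraries. In all 10 of these genes the 3 MT values lay on 1 side of the 3 Control values, as they did in 1229 of the 10950 genes (11.2%, where chance gives 10%). Positions are those of the Sscrofa11.1 assembly for the gene of that symbol.

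Control replicate 3 stood apart from the other 5 libraries. On the principal component that held 68.2% of the variance it lay at 40.4, against -22.0 and -21.7 for the other Control libraries and -10.4 to 7.5 for the MT libraries. The component with 16.5% of the variance parted the groups, with the Control libraries at 6.5 to 12.3 and the MT libraries at -13.7 to -7.6. The correlation across genes of Control 3 with Control 1 and Control 2 was 0.938 and 0.939, while Control 1 and Control 2 had 0.993, and genes are not independent replicates. With MT 1, MT 2 and MT 3 it was 0.975, 0.952 and 0.971, so Control 3 lay closer to each MT library than to its own group. Its mitochondrial mRNAs took 2.72% of reads, against 4.35% to 5.56% in the other 5 libraries. Without Control 3, 1194 of the 10950 genes passed in limma, of which 469 rose and 725 fell, and 60 of them changed at least 2-fold (16 up and 44 down). Of the 1194 genes, 1153 had the same direction over all 6 libraries, and 275 had values that did not overlap between the groups of 3. The shared direction was largely fixed, since 5 of the 6 libraries made the call. Against the mean of the other 5 libraries, Control 3 had a median log2 deviation of 0.24 in the genes that rose and -0.60 in those that fell. The library left out thus typically lay on the MT side of these genes. The share that rose was 39.3%, and 49.7% when those 5 libraries were quantile normalised. Leaving out any other library passed 0 genes, with 249 to 427 genes under an unadjusted p of 0.05. With all 6 libraries, limma sample weights, which gave Control 3 a weight of 0.05 with a convergence warning, passed 6309 genes. A term for the main component within groups passed 714, and up to 5539 when the libraries were split otherwise.

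**Figure D1:**
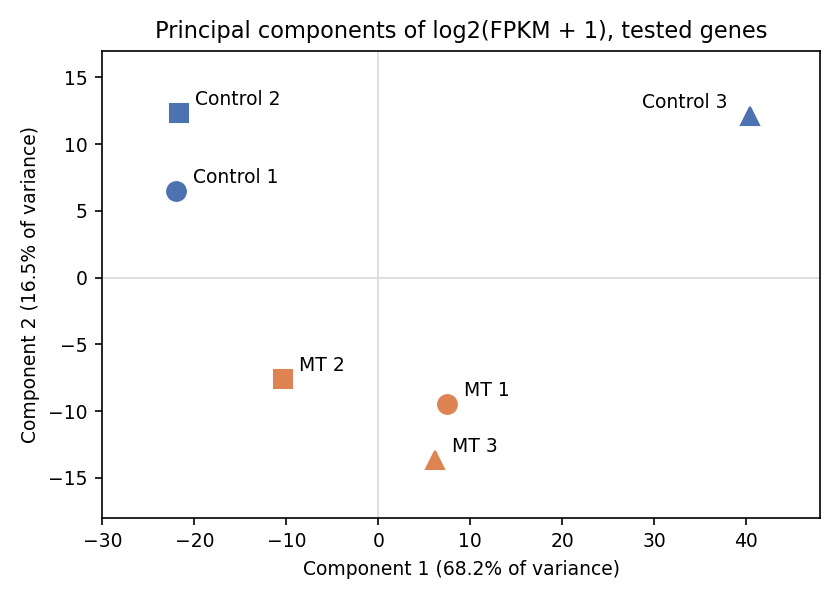
Principal components of log2(FPKM + 1) over the 10950 tested genes, with a point per library, coloured by group and shaped by replicate number. Component 1 (68.2% of variance) sets Control 3, at 40.4, apart from the other libraries, and component 2 (16.5%) places the 3 Control libraries above 0 and the 3 MT libraries below 0.

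Of 39 gene lists fixed beforehand, 36 had at least 3 tested members, and 12 of them passed the camera test of limma with its preset correlation, 4 upward and 8 downward. With a correlation estimated from the data, 3 of the 12 passed: cholesterol synthesis and uptake, glutamine, serine and one-carbon metabolism, and S phase and replication, each with an adjusted p of 0.040. The directional test fry passed the cholesterol and glutamine lists (adjusted p 0.020 each), and gave 0.065 for S phase. Without Control 3 the preset test passed 10 lists, fry passed 4, which were cholesterol, glutamine and apoptosis (adjusted p 0.048 each) and the extracellular matrix (0.017), and with an estimated correlation every list had an adjusted p of at least 0.78. With an estimated correlation 0 lists also passed without Control 1, Control 2, MT 1 or MT 2, and the cholesterol and glutamine lists passed without MT 3 (0.049 each). The test fry passed 0 lists without Control 1, Control 2 or MT 1, the cholesterol list without MT 2 (0.037), and both lists without MT 3 (0.014 each). No member of any list passed over all genes tested, so the counts of members that follow are those adjusted over the list alone or those without Control 3.

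**Figure D2:**
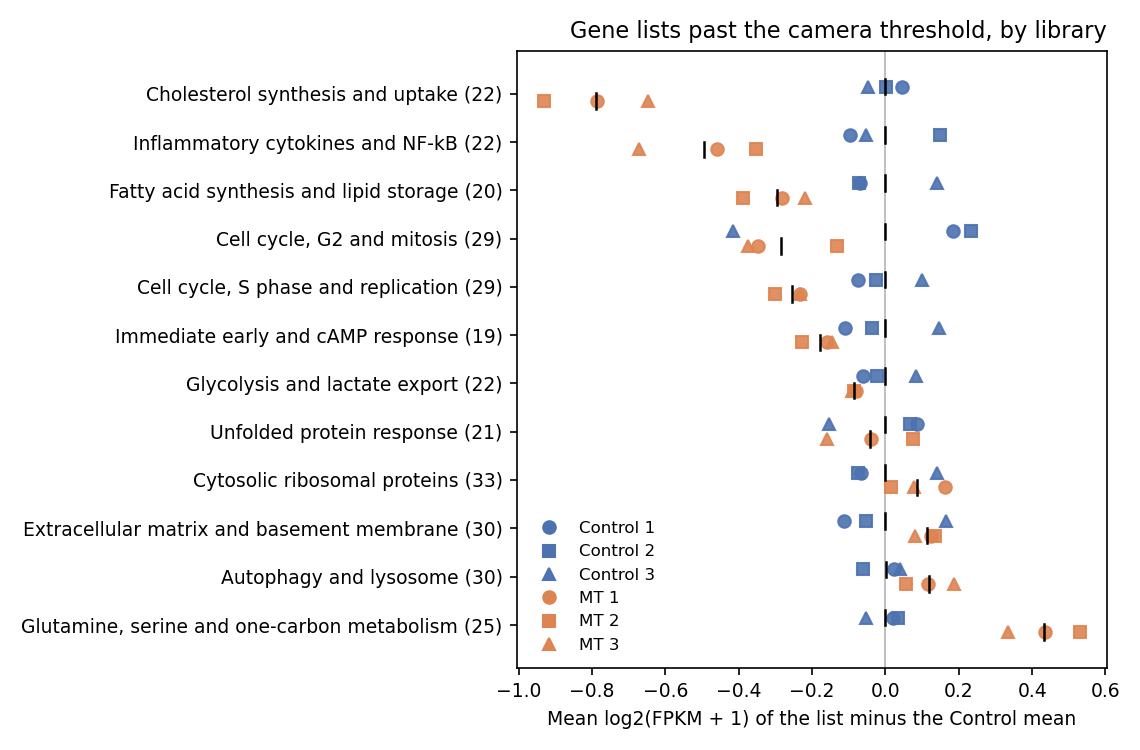
Mean log2(FPKM + 1) of the 12 gene lists past the preset camera test, per library, relative to the mean of the 3 Control libraries, with the number of tested members in brackets and a black bar at each group's mean. The 3 MT libraries lie from -0.93 to -0.65 for cholesterol synthesis and from 0.33 to 0.53 for glutamine, serine and one-carbon metabolism, and Control 3 lies below the MT libraries for G2 and mitosis, at -0.42 against -0.37 to -0.13.

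In the cholesterol list (adjusted p 4.6e-36 with the preset correlation), 18 of 22 members passed adjusted over the list alone, all of them lower in MT. INSIG1 (ENSSSCG00000016420) lies on chromosome 18 from 2885494 to 2898758 and had a log2 difference of -1.43 (SE 0.15). ACAT2 (chromosome 1, 7600616 to 7612861), which joins acetyl-CoA units in the cytosol, stood at 21.9 ± 1.58 FPKM in Control and 9.28 ± 1.65 in MT. HMGCS1 (chromosome 16, 27936225 to 27957261), which makes HMG-CoA, stood at 50.3 ± 16.3 and 15.4 ± 2.0 (both n = 3), a log2 difference of -1.59 (SE 0.25). Without Control 3 the list median was -0.79 and 17 members fell over all genes tested, among them HMGCS1 (-1.88), INSIG1 (-1.37) and ACAT2 (-1.11). Named after their values were seen, MSMO1 (-1.48), IDI1 (-1.32) and SQLE (-1.30), enzymes further along the pathway, also fell without Control 3.

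**Figure D3:**
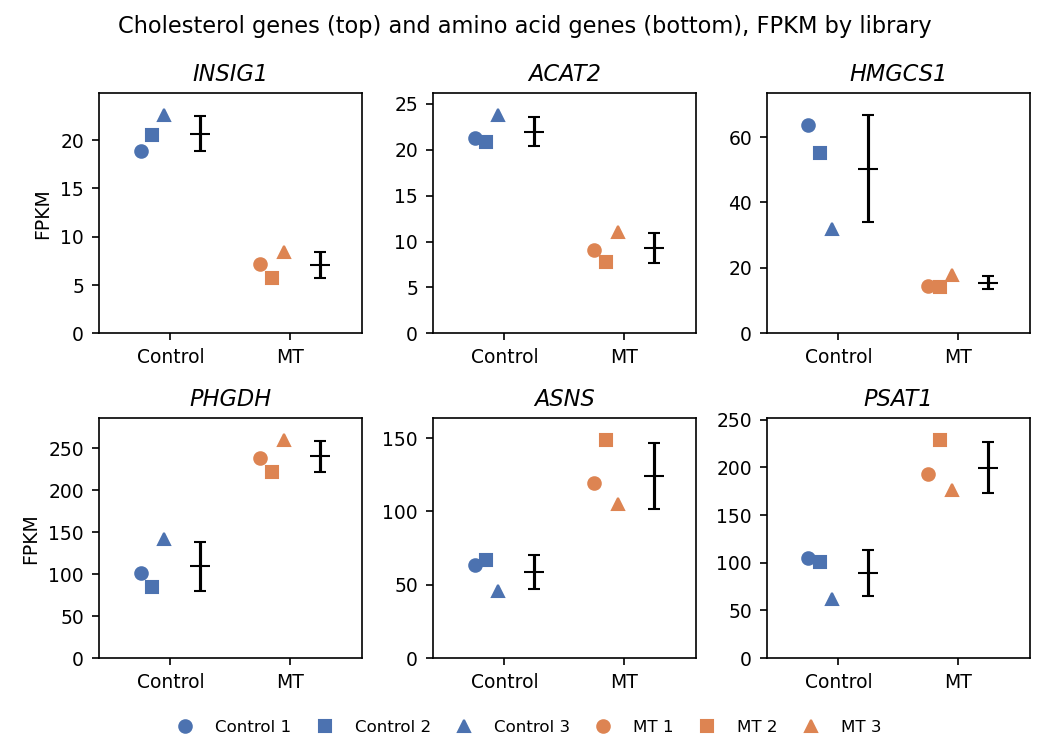
FPKM of 3 cholesterol genes (top) and 3 amino acid genes (bottom), with a point per library and the mean ± SD of each group of 3 in black. In each of these genes the 3 MT values lie on 1 side of the 3 Control values, as for INSIG1 with means of 20.7 in Control and 7.10 in MT, and no gene passed the test over all 10950 genes with 6 libraries.

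The list of fatty acid synthesis and lipid storage fell in the preset test, with a median of -0.27 and 16 of 20 members lower (adjusted p 4.3e-10), and had an adjusted p of 0.17 with an estimated correlation. Adjusted over the list alone, 3 members passed. Beside SCD, ACSS2, which makes acetyl-CoA from acetate, stood at 8.07 ± 1.26 FPKM in Control and 4.59 ± 0.65 in MT, and the desaturase FADS1 at 147.7 ± 17.8 and 100.5 ± 3.97. FADS2 stood at 86.0 ± 15.5 and 58.4 ± 5.52 (all n = 3). Without Control 3, 8 members fell and 1 rose, and SCD (-1.39), ACSS2 (-0.59), FADS1 (-0.45) and FADS2 (-0.40) were among those that fell. In Control 3 the members lay a median of 0.30 above Control 1 and Control 2.

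In the list of glutamine, serine and one-carbon metabolism (adjusted p 1.4e-11), 8 of 25 members passed adjusted over the list alone, all of them higher in MT. PHGDH (ENSSSCG00000006717, chromosome 4, 101445977 to 101478144) had a log2 difference of 1.16 (SE 0.19). PSAT1 (chromosome 1, 231142673 to 231172364), the next enzyme of serine synthesis, stood at 89.3 ± 24.1 FPKM in Control and 199.4 ± 26.7 in MT. ASNS (chromosome 9, 77318341 to 77336290), which makes asparagine, stood at 58.7 ± 11.4 and 124.2 ± 22.3, and GPT2 (chromosome 6, 37625428 to 37669695), a mitochondrial alanine aminotransferase, at 15.6 ± 1.88 and 24.8 ± 1.57 (all n = 3). Without Control 3 the list median was 0.34 and 12 members rose over all genes tested, among them PHGDH (1.36), PSAT1 (0.94), ASNS (0.91) and GPT2 (0.72).

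The list of inflammatory cytokines and NF-kB fell in the preset test, with a median of -0.46 and 21 of 22 members lower (adjusted p 5.1e-20), and had an adjusted p of 0.15 with an estimated correlation. Adjusted over the list alone, 4 members passed. NFKBIA, the inhibitor that holds NF-kB in the cytoplasm, stood at 65.3 ± 10.3 FPKM in Control and 34.3 ± 3.65 in MT, and TNFAIP3, which also damps NF-kB signalling, at 6.38 ± 1.03 and 3.46 ± 0.37. The chemokine CXCL2 stood at 29.5 ± 5.37 and 13.4 ± 2.34 (all n = 3), and TNFAIP2 had a log2 difference of -0.70 (SE 0.15). Without Control 3, 10 members fell, NFKBIA (-0.82), CXCL2 (-1.02), TNFAIP3 (-0.73) and TNFAIP2 (-0.61) among them. The list of immediate early and cAMP response genes had a median of -0.19 and fell in the preset test (adjusted p 3.8e-04), but its adjusted p was 0.56 with an estimated correlation and 0.55 in the preset test without Control 3. IER3 stood at 123.4 ± 22.9 and 62.1 ± 9.31 FPKM and fell without Control 3 (-1.04). FOSL1 at 14.6 ± 4.03 and 8.44 ± 0.83, MYC at 70.2 ± 10.2 and 51.3 ± 2.62 and JUNB at 105.3 ± 16.2 and 81.7 ± 2.63 did not pass in either fit.

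The list of S phase and replication (adjusted p 6.1e-13) had 0 of 29 members past the test adjusted over the list alone, and 8 members fell without Control 3. GINS1, a part of the replicative helicase complex, stood at 10.0 ± 0.72 FPKM in Control and 7.19 ± 0.64 in MT, and ORC1, a part of the origin recognition complex, at 14.9 ± 0.90 and 11.7 ± 0.43, and both fell without Control 3 (-0.49 and -0.36). The thymidine kinase TK1 stood at 29.7 ± 8.49 and 19.1 ± 3.37 and the helicase subunit MCM4 at 64.7 ± 12.1 and 48.6 ± 2.32 (all n = 3), and neither passed. The list of G2 and mitosis fell in the preset test, with a median of -0.29 and 28 of 29 members lower (adjusted p 5.9e-11), and had an adjusted p of 0.39 with an estimated correlation. Its members lay a median of 0.69 lower in Control 3 than in the other Control libraries, below all 3 MT libraries in the list mean. The median was -0.14 without Control 1 and -0.11 without Control 2, with preset adjusted p of 1.4e-06 and 4.2e-06. Without Control 3 the median was -0.52 and 20 members fell, among them KIF20A (-0.40), AURKB (-0.44), BIRC5 (-0.42) and KIF2C (-0.28), which act in chromosome segregation and cell division. Over 6 libraries KIF20A stood at 32.0 ± 0.94 FPKM in Control and 24.4 ± 0.89 in MT, and AURKB at 14.8 ± 1.84 and 9.92 ± 1.13.

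The list of the extracellular matrix and basement membrane rose in the preset test, with a median of 0.16 and 22 of 30 members higher (adjusted p 1.8e-03), and had an adjusted p of 0.56 with an estimated correlation and 0.38 in the preset test without Control 1. The collagen genes COL1A2 and COL4A2 stood at 2749 ± 111.9 and 200.6 ± 6.96 FPKM in Control and 3449 ± 51.4 and 251.5 ± 11.5 in MT, and COL5A1 at 119.9 ± 7.07 and 146.3 ± 2.87 (all n = 3). These 3 rose without Control 3, as did 12 members in all, and the list median was then 0.26 (preset adjusted p 4.8e-05). In Control 3 the members lay a median of 0.29 above Control 1 and Control 2.

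Another 2 lists rose in the preset test, each with an adjusted p of 0.034 there and 0.56 with an estimated correlation. Autophagy and lysosome genes had a median of 0.11, with 24 of 30 members higher. WIPI1 stood at 4.64 ± 0.48 FPKM in Control and 6.26 ± 0.24 in MT, GABARAPL1 at 20.9 ± 1.58 and 27.2 ± 2.89, and HEXA at 20.6 ± 1.51 and 25.3 ± 1.08, while NPC1, which moves cholesterol out of lysosomes, stood at 8.82 ± 0.35 and 6.16 ± 0.30 (all n = 3). Without Control 3, HEXA rose (0.34) and NPC1 fell (-0.44). The adjusted p of this list was 0.11 without Control 1, 0.32 without Control 2, 0.056 without MT 1 and 0.11 without MT 3. Cytosolic ribosomal protein genes had a median of 0.10, with 27 of 33 members higher. RPL3 stood at 1010 ± 68.7 and 1160 ± 28.1 FPKM and rose without Control 3 (0.26), and RPL35 and RPS4X had log2 differences of 0.17 and 0.14 and did not pass in either fit. The list median was 0.20 without Control 3, where the preset adjusted p was 1.2e-03, and 0.045 and 0.049 without Control 1 and Control 2. The adjusted p was 0.43 without Control 1, 0.32 without Control 2 and 0.40 without MT 1. Ribosomal protein genes have many processed copies in the genome, which can share reads with them, so these values are uncertain.

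The lists of glycolysis and lactate export and of the unfolded protein response fell in the preset test, with medians of -0.06 and -0.09 and adjusted p of 0.020 and 0.034, and each had 0.56 with an estimated correlation. For glycolysis the median turned to 0.01 and the preset adjusted p to 0.92 without Control 3, in which the members lay a median of 0.31 above Control 1 and Control 2. The median was -0.09 without Control 1 or Control 2 and -0.035 without MT 3. Hexokinase HK2 stood at 39.5 ± 5.55 FPKM in Control and 32.4 ± 0.73 in MT, and PFKFB3 at 11.6 ± 1.38 and 9.83 ± 0.33. LDHB at 3.18 ± 0.56 and 2.32 ± 0.05 and GAPDH at 2.08 ± 0.55 and 1.51 ± 0.11 were far below the level usual for these enzymes, and copies of these genes can share reads with them, so their values are uncertain (all n = 3). None of the 4 passed in either fit. The members of the unfolded protein response list moved apart. HSPA5, the main chaperone of the endoplasmic reticulum, stood at 818.2 ± 40.6 FPKM in Control and 523.3 ± 46.1 in MT and calreticulin (CALR) at 581.7 ± 14.0 and 451.5 ± 15.1, while CHAC1, which degrades glutathione, stood at 12.0 ± 2.40 and 29.4 ± 8.87 and the pseudokinase TRIB3 at 14.9 ± 1.78 and 26.0 ± 6.08 (all n = 3). These 4 passed adjusted over the list alone, and without Control 3 HSPA5 (-0.69) and CALR (-0.35) fell and CHAC1 (1.33) and TRIB3 (0.84) rose. Without Control 3, 7 members fell and 2 rose, and the median was -0.18 there (preset adjusted p 0.039) and without MT 2 (6.7e-03). The preset test of this list gave 0.31 without Control 1, 0.18 without Control 2 and 0.46 without MT 3, with medians of -0.05, -0.05 and -0.04, and the list mean of -0.04 turned to 0.002 without Control 1 and 0.02 without MT 3.

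The other 24 tested lists did not pass. Sertoli cell identity genes had a median of 0.04 over 11 members, with 6 higher and 5 lower, and lists of secreted growth factors (-0.03), inhibin, activin and AMH signalling (0.01) and tight junctions (0.03) had medians near 0. SOX9 and WT1, transcription factors of Sertoli cells, stood at 2.13 ± 0.30 and 10.6 ± 0.54 FPKM in Control and 1.68 ± 0.11 and 11.5 ± 1.30 in MT, and AMH, the hormone that makes the Mullerian duct regress, at 13.4 ± 2.16 and 12.2 ± 0.53. INHBB, an inhibin subunit, was at 4.01 ± 0.94 and 4.23 ± 0.59, the gap junction gene GJA1 at 5.81 ± 1.44 and 6.28 ± 1.92, and the cyclin gene CCND1 at 53.4 ± 4.88 and 47.5 ± 1.41. LDHA, which makes lactate, was at 422.3 ± 64.1 and 407.4 ± 28.8, and its exporter SLC16A3 at 88.7 ± 18.6 and 81.4 ± 6.26 (all n = 3). Superoxide dismutase SOD2 was at 35.8 ± 9.22 and 24.9 ± 2.04 and fell without Control 3 (-0.67), and the antioxidant list had a median of 0.00 and an adjusted p of 0.062 in preset camera, with 0.045 without Control 1, 0.050 without Control 2 and 0.048 without MT 1, all downward. With an estimated correlation the antioxidant list had 0.37, and it did not pass there without Control 1, Control 2 or MT 1. GDNF, KITLG and INHA were under the mean of 1 FPKM needed for testing. MTNR1A, MTNR1B, FSHR, CLDN11, CDH2, SLC2A1 and BCL2 were not analysed here.

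Markers of other testis cell types had medians of 0.12 for peritubular myoid cells (9 tested members), 0.05 for fibroblasts and stroma (4), 0.08 for macrophages and leukocytes (5) and -0.05 for steroid synthesis and Leydig cells (8). Their adjusted p values in preset camera were 0.18, 0.74, 0.48 and 0.51, and the myoid list gave 0.010 without MT 3. With an estimated correlation the myoid list had 0.56 over 6 libraries and did not pass without MT 3. Germ cell and endothelial markers had 2 tested members each and erythroid markers 0, too few for the test.

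The 13 protein-coding genes of the mitochondrial genome are called mRNAs here, although ATP8 and ATP6 share an mRNA, as do ND4L and ND4. They had a median of 0.14 and an adjusted p of 0.091 in preset camera, with 0.78 with an estimated correlation. They lay a median of 0.97 lower in Control 3 than in the other Control libraries. CYTB stood at 844.3 ± 171.6 FPKM in Control and 2169 ± 363.9 in MT (n = 3), a log2 difference of 1.37 (SE 0.20, adjusted p 0.245 in limma). Without Control 3, CYTB rose (1.19) while COX3 (-0.73), ND5 (-0.61), ND6 (-1.06) and ATP8 (-2.37) fell. ATP6, on the same mRNA as the 204 bp ATP8, then differed by -0.06, so the ATP8 value is not read as a change of that mRNA. The ratio of ATP8 to ATP6 was 0.153, 0.142 and 0.019 in Control 1 to 3, and 0.021 to 0.057 in MT. In the preset test the adjusted p of the list was 2.1e-03 without Control 1, 2.5e-03 without Control 2 and 5.3e-03 without MT 3, each upward, and 0.60 to 0.80 in these 3 fits with an estimated correlation. Without Control 3 the list pointed downward, with a median of -0.06 and an adjusted p of 0.55 in the preset test. Copies of mitochondrial genes in the nuclear genome can share reads with them.

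**Figure D4:**
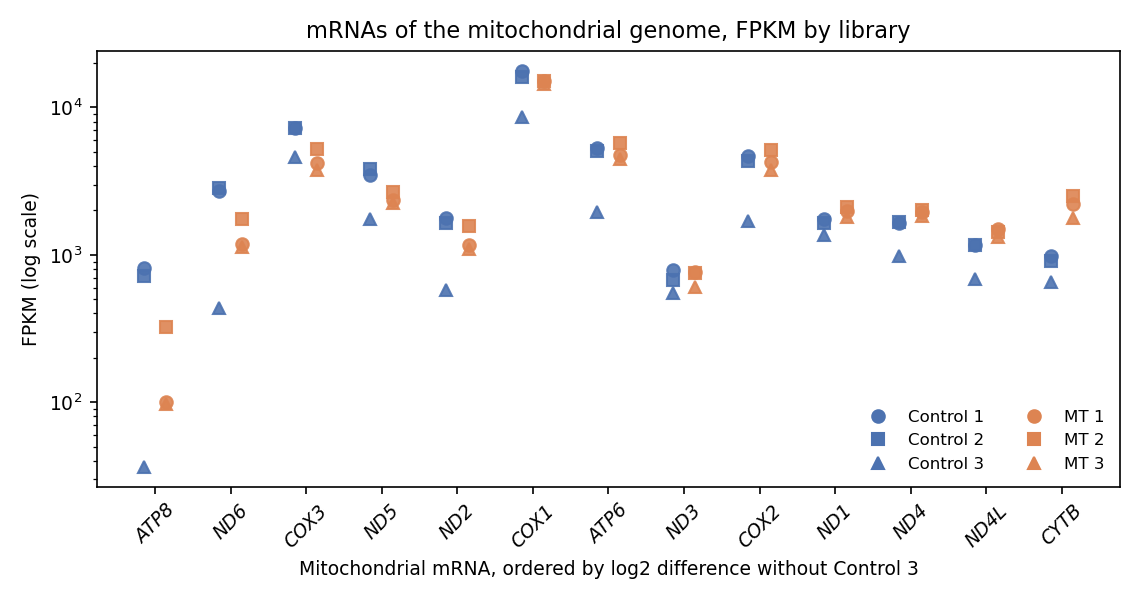
FPKM of the 13 mitochondrial mRNAs on a log axis, with a point per library, ordered by the log2 difference between MT and Control without Control 3. Control 3 has the lowest value of the 6 libraries for most of these mRNAs, at 36.5 FPKM for ATP8 against 97.3 to 818.4 in the others, and the 3 MT values of CYTB, 1781 to 2502, lie above the 3 Control values, 651.0 to 978.3.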

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

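The voom, mitochondrial scaling, within-group component, gene length and 5-library fits, and the set tests other than preset camera with a library left out, were chosen after seeing the data. The count of 0 genes (0 at 2-fold) held under every other pseudocount, filter, scaling and variance model, with 332 to 995 genes under an unadjusted p of 0.05. Sample weights gave 6309 genes (111 at 2-fold), with weights of 0.05 for Control 3 and 4.96 for MT 1 and a convergence warning. The within-group component as a term gave 714 (34), of which 470 were among the 1194 called without Control 3, and the same procedure on other splits of the libraries gave up to 5539. Leaving out a library gave 0 to 1194 genes (0 to 60), the highest without Control 3, and for lists 10 to 12. Those 5 libraries gave 1113 (73) scaled to a common sum, 1210 (59) by median of ratios, 1333 (62) by quantiles, 1155 (60) scaled outside the mitochondrial genome, 1355 (59) with the length trend removed, and 2369 (94) by voom, which included 1141 of the 1194. For all of these the cause was not tested. Of 36 lists, 12 passed, against 3 with an estimated correlation and 2 with fry, whose constructions allow for correlated genes, and 8 to 14 over the other settings at the preset correlation, the lowest by quantiles without Control 3. The estimated correlation of the glutamine list was 0.01, the same as the preset, yet its adjusted p went from 1.4e-11 to 0.040 in camera. Correlation between genes therefore does not account for that change. Camera with an estimated correlation takes its degrees of freedom from the few libraries, and the preset test from the genes. The fall from 12 lists to 3 is thus not a measure of correlation between genes alone. Leaving out a library lowers the degrees of freedom further, so a call lost that way does not show that the list rested on that library. With a library left out as well, 0 to 2 lists passed with an estimated correlation (0 without Control 3) and 0 to 4 with fry (4 without Control 3). The cholesterol and glutamine lists passed in the 25 settings that changed at most 1 choice, the reported one included, with means of -0.89 to -0.72 and 0.38 to 0.48, and S phase in 24. With a library left out as well, both passed with an estimated correlation without MT 3 but not without any other library (adjusted p 0.093 to 0.78), and with fry both passed without Control 3 or MT 3, and cholesterol without MT 2. The sign changed in some of these settings for 4 of the 64 named genes, which are GJA1 (-0.18 to 0.28), INHBB (-0.04 to 0.22), LDHA (-0.21 to 0.05) and SLC16A3 (-0.20 to 0.06), and for the means of 17 of the 36 lists, 16 of which had not passed, among them the mitochondrial genome (-0.31 to 0.39). The other was the unfolded protein response (-0.12 to 0.02). None of these genes and lists passed in a setting where its sign was turned. The replicate block gave 0 genes and 12 lists. Same-numbered libraries deviated together with correlations of -0.44, 0.63 and 0.34, so the numbers were not read as pairs, and not every library correlated best with its own number.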

Other observations

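The tests of depth, length, label and Control 3 alone, of the mitochondrial mRNAs, of single-gene counts and of 4 further gene families, and the set tests with a library left out, were chosen after the results were seen, while the mitochondrial scaling tests and the splits for lists were set before theirs.

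Beyond the fixed lists, 4 gene families were tested as hypotheses raised by these values. Aminoacyl-tRNA synthetase genes, which load amino acids onto tRNA, were higher in MT, with a median of 0.25 over 19 genes, 15 of them higher, and a median of 0.12 without Control 3. The directional test fry gave an adjusted p of 0.022 over the 4 lists, camera with an estimated correlation gave 0.028, and fry gave 0.084 without MT 1 and 0.10 without MT 2. The call with an estimated correlation was lost without Control 1, Control 2, Control 3 or MT 1 (adjusted p 0.059 to 0.16). Here and below, fits with a library left out have fewer degrees of freedom, so a lost call does not single out that library. WARS1 stood at 75.1 ± 10.4 FPKM in Control and 124.0 ± 11.7 in MT (n = 3), with 6 members past limma's threshold without Control 3. Target genes of the transcription factor ATF4 outside the amino acid list had a median of 0.39, with 13 of 15 higher and a fry adjusted p of 0.037, but an adjusted p of 0.057 with an estimated correlation, which passed without MT 3 (0.047) and not without any other library (0.074 to 0.16). With a library left out, fry gave 0.012 without Control 3, 0.030 without MT 3 and 0.13 to 0.15 without each of the others. They include NUPR1, CHAC1 and TRIB3, and 6 of the 15 also stand in fixed lists. The glycine transporter SLC6A9 stood at 15.5 ± 4.09 and 27.9 ± 2.33 FPKM. Chaperones of the endoplasmic reticulum had a median of -0.24, with 12 of 14 lower, and small nucleolar RNAs a median of -0.24, with 24 of 31 lower, and each had a fry adjusted p of 0.091, which did not pass. Without Control 3 fry gave 0.012 for both, and 0.13 to 0.29 without each of the others, and with an estimated correlation over 6 libraries camera gave an adjusted p of 0.051 for the chaperones and 0.031 for the small nucleolar RNAs. The latter call was lost without Control 1, Control 2, Control 3 or MT 1 (0.060 to 0.16). The medians were -0.35 for the chaperones and -0.52 for the small nucleolar RNAs without Control 3. Among the small nucleolar RNAs with the smallest p, SNORD38A, SNORD99, SNORD93 and SNORA27 had 0 reads in at least 1 library. SNORD86 and SNORD12B had as few as 13 and 23, so counting error is large in these short RNAs. Of the 14 chaperone genes, 12 stand in the unfolded protein response list. Without Control 3, 8 chaperone genes fell and 0 rose. A candidate explanation is that the amino acid genes belong to a wider ATF4 response, separate from the chaperone genes. It rests on the genes that raised it, and the difference between the chaperone and ATF4 lists was not itself tested.

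Cholesterol genes were lower and amino acid genes higher in every MT library than in every Control library when averaged over the list. A trend with gene length did not account for it, since 95.9% or more of each list's mean log2 change was left once the trend was removed. Both lists then still passed preset camera. Scaling outside the mitochondrial genome left 99.2% or more, so dilution by mitochondrial reads was too small to make these means. It multiplies each library by 1 factor, which moves all genes nearly alike, so that both lists again passed preset camera was nearly fixed and is no further support. Leaving out Control 3 left 93.8% or more of the means, with both lists past preset camera and fry (adjusted p 0.048 each) but at an adjusted p of 0.78 with an estimated correlation, a call that was also lost without Control 1, Control 2, MT 1 or MT 2, so Control 3 alone does not account for the means. The mean log2 change of the cholesterol list was -0.79, and the highest of the other 9 splits gave 0.39 in size (1 of 10 splits as large), while 12 lists passed against up to 8 in other splits (1 of 10), and 10 splits are too few for a share under 0.05. Without Control 3 the real groups passed 10 lists in preset camera, and MT 1 and MT 2 against the rest also passed 10. GC content was not tested, and melatonin itself, its solvent, the time in culture, a batch shared within a group and GC content remain open.

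Control 3 differed from the mean of the other libraries by a root mean square of 0.48 on the log2 scale, against 0.19 to 0.30 for each other library. Its total of 20961380 reads lay inside the range of the others, and 96.2% of its distance was left after the length trend was removed. After scaling outside the mitochondrial genome 103% was left, nearly fixed since this multiplies each library by 1 factor. None of these alone accounts for the distance. An MT library under a Control label is argued against by its cholesterol list, 0.60 above the highest MT library where the 3 MT libraries had an SD of 0.14. Its glutamine list also lay with Control, at -0.05 against 0.33 to 0.53 in MT. Its G2 and mitosis list lay beyond MT, at -0.42 against -0.37 to -0.13. Over all tested genes it correlated more with each MT library than with Control 1 or Control 2. A wrong label is therefore not excluded. A different state of its cells, its RNA quality or its library preparation may be the source, and no biological explanation was tested. Over 6 libraries the real groups gave 0 genes, so 10 of 10 splits gave at least as many by construction, in all and at 2-fold (highest other 1). This comparison of adjusted counts decides nothing. At an unadjusted p under 0.05 in limma, Control 1, Control 2 and MT 2 against the rest gave 4301 genes, against 517 for the real groups. The largest difference between these libraries thus cut across the groups. The same split appeared in each library's Spearman rho with gene length, at 0.16, 0.14 and 0.19 in Control 1, Control 2 and MT 2. It was -0.21, -0.13 and -0.03 in Control 3, MT 1 and MT 3, though removing the length trend left most of the distance of Control 3. Without Control 3, 2 of 10 splits gave as many as 1194, with 1414 for MT 1 and MT 3 against the rest, which points to a structure of the libraries besides the groups, and 10 splits are too few for a share under 0.05.

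Some mitochondrial mRNAs moved apart between the groups, as in the ratio of CYTB to COX3, which was 0.125 to 0.141 in the 3 Control libraries and 0.474 to 0.530 in the 3 MT libraries. A single change in the share of mitochondrial RNA would leave such ratios alike, but 16 of the 78 ratios between the 13 mRNAs differed in limma over 6 libraries (adjusted over the ratios), with 2 to 56 when a library was left out, the most without Control 3 and the fewest without Control 1 or MT 1. Control 1, Control 2 and MT 2 against the rest also gave 16, so the ratios differ between libraries besides the groups. All 16 ratios that differed between the real groups contain CYTB, COX3 or ND5, so these mRNAs are counted repeatedly. The ratios of ATP8 to ATP6 and of ND4 to ND4L, pairs on a shared mRNA, did not differ (adjusted p 0.38 and 0.72 in limma). Relative to the mean of the 13, CYTB alone passed in limma (adjusted p 0.037). In that test 10 passed without Control 3 and 0 without any other library. Control 1, Control 2 and MT 2 against the rest gave 5 there. A smooth trend with length is argued against as the whole cause, since CYTB and COX3, 2 of the 11 mRNAs longer than 300 bp, still differed once it was removed (adjusted p 6.2e-03 and 0.014), with 8 without Control 3 and 1 when any single MT library was left out. Changes in the processing or stability of single mitochondrial transcripts, whether counting used strand, and copies in the nuclear genome remain open.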
